A study of Homo sapiens with 3 samples.

How the data were processed

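RNA-seq libraries were made from total RNA of H446 cells after 48 h with vehicle, 5 µM BAS or 10 µM BAS, per the labels' protocols, and sequenced as single-end reads of 50 bases on an MGISEQ2000. There was 1 library per group and 3 in all. Per the submitters' processing notes, the authors used Trim Galore, BWA, Bowtie2, Cufflinks and Cuffdiff and the human genome build hg19. Versions, the role of each tool, the annotation and any scaling between libraries are not given in the sources used here. The deposited values are FPKM per the file headers, and the files are titled RPKM, which is the same quantity for single-end reads. The values have 2 decimals. Each file holds 16795 rows for 16793 gene symbols, and the 2 symbols listed in more than 1 row were summed. These look like dates, as a spreadsheet writes the names of some genes, so that each sum joins different genes. They belong to 22 date-like symbols, and 39 symbols are numbers alone. There were 27 rows at 0 in all 3 libraries at once. The values sum to 487923 to 507342 FPKM per library. The low values gave no whole-read steps from which depth could be recovered, so the depth is unknown and no counting error can be given.

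Groups and doses were taken from the treatment labels and file titles. Per the file headers, the value columns of the treated libraries carry the codes ASB85 and ASB810 where the labels say BAS at 5 and 10 µM. Whether these codes mean those doses could not be checked, and every dose value rests on it. Gene values were compared as log2(FPKM + 1) among the 11512 genes with a mean of at least 1 FPKM over the 3 libraries. Before the data were examined, the rule of size was set at an absolute log2 difference of at least 1, since 1 library per group allows no test. The design had assumed RPKM, which needs the same treatment. Also set beforehand were 40 gene lists, covering MAPK signalling, the cell cycle, stress responses, metabolism, cell identity and cells foreign to the culture. For each list with at least 5 members past the filter, the median difference was placed among 10000 random lists of the same size, drawn from the same 20 expression bins with a fixed seed. The 95% interval of a list median is an order-statistic interval over members, which share libraries and are not independent. To judge agreement between doses, 100 sets of unchanged libraries were simulated with the spread of each expression bin, taken from the 10 µM against 5 µM differences and divided by the square root of 2. That spread includes real dose effects, but it is a robust estimate that gives little weight to extreme genes. Over all genes it was 0.148 between doses before that division, where the standard deviation was 0.178. It comes from the treated libraries alone, so it does not measure how the vehicle library varies, and it is not an upper limit.

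Named genes follow a rule set beforehand: the 10 highest and 10 lowest differences at each dose against vehicle, the 5 highest and 5 lowest between doses, up to 4 members of each list with the largest difference at 10 µM, the ERK output genes, 6 kinase genes, MYC, NEUROD1, DHODH, UQCRFS1, and the 5 highest and 5 lowest dose-ordered genes. Symbols of small or uncharacterised RNAs, numbers, XIST and Y-linked genes were left out. The rule gave 182 genes. ASNS, CHAC1, DDIT4, HSP90B1, DNAJB11, SEC61B, CREB3L2, MCM2, PCNA, POLA1, CDKN1A, CTGF, XPC, HIST1H1C, HIST2H2AA3 and the genes that open the other observations lie outside it and were chosen after their values were seen.

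Transcript length, GC content and shared 50-base sequences came from the longest protein-coding transcript per symbol in GENCODE 29, a GRCh38 annotation. It was matched by symbol, for 11363 of the 11512 genes (98.7%), and 271 of these (2.38%) shared at least 50% of their 50-base sequences with another gene. Because the authors' build is hg19, no coordinates are given. The alternatives tried were pseudocounts of 0.1 and 0.5, no filter, a filter at 5 FPKM, fold limits of 1.5 and 4, median-ratio scaling, rescaling to a common total, quantile normalization, duplicated symbols left out, list means and unmatched random lists. Removal of GC and length trends, genes with under 50% shared 50-base sequences, and lists without ATF4 list members were added after the data were seen. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

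The steps were tested on simulated data for 10 µM against vehicle, with some of the 11512 genes shifted. The rule of size called 0% of the 50 genes shifted 1.5-fold, 60% of the 50 shifted 2-fold, and 98% of the 50 shifted 3-fold and of the 50 shifted 4-fold. These shifts were made on the log2(FPKM + 1) scale, so the rates are lower for low genes with plain FPKM ratios of that size. It called 0 of 11312 unshifted genes. That count was fixed in advance, because the simulated spread of a library was at most 0.134 against a limit of 1. It therefore gives no error rate for the real libraries. Of 100 simulated lists of 25 members, 2% stood apart with no shift, 70% with a shift of 0.1 on the log2 scale and 100% with a shift of 0.25. The members were drawn at random with independent noise, so a low rate with no shift was also fixed in advance. These rates give no error rate for the real lists, whose genes are not independent.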

Results

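RNA was sequenced from H446 cells, a line derived from human small cell lung cancer, after 48 h with vehicle or with 3-bromoascochlorin (BAS), a brominated derivative of the fungal metabolite ascochlorin, at 5 µM or 10 µM. The title given to the study names antitumor effects of the compound and the MAPK pathway, the kinase cascades that carry growth factor and stress signals, so the comparisons set each dose against vehicle and the doses against each other. There were 3 libraries, 1 per group, so no difference has a replicate check and no test or p-value is given. Each library held a value for 16793 gene symbols, and the values summed to 487923 FPKM with vehicle, 507342 at 5 µM and 492102 at 10 µM. The read depth is unknown, because the files hold FPKM without counts. Among the symbols, 11425, 11483 and 11545 were at or above 1 FPKM in the vehicle, 5 µM and 10 µM library. Comparisons used the 11512 genes with a mean of at least 1 FPKM over the 3 libraries. A gene is called 2-fold higher or lower where its log2(FPKM + 1) differed by at least 1, a scale that understates the differences of low genes, while folds in the text are plain ratios of FPKM. Values of a gene are given in the order vehicle, 5 µM and 10 µM.

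At 5 µM, the genes furthest above vehicle were led by stress hormones and stress regulators. GDF15, a stress-induced cytokine, was at 3.60 FPKM with vehicle and 40.43 FPKM at 5 µM, and FGF21, a secreted metabolic hormone, at 4.93 and 38.43 FPKM. TRIB3 and DDIT3 (CHOP), regulators in the response to amino acid and protein folding stress, were 3.90-fold and 3.44-fold higher. The membrane protein gene EMP1, the AP-1 family gene JDP2, GSG1 and the polyamine-degrading enzyme gene SAT1 were also among the highest. The lowest genes included the histone genes HIST1H2AC, HIST1H2BK, HIST1H2BD and HIST2H4A, the keratin genes KRT8 and KRT18, the spindle gene ASPM and the phosphatase regulator gene PPP1R10. PPP1R10 was at 26.71 FPKM with vehicle and 9.25 FPKM at 5 µM, and KRT8 at 4.81 and 1.12 FPKM. In all, 62 genes were at least 2-fold higher and 24 at least 2-fold lower. With a pseudocount of 0.1 in place of 1 these counts were 143 and 53.

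At 10 µM, GDF15 reached 62.59 FPKM, 17.4-fold over vehicle, and FGF21 53.94 FPKM, 10.9-fold over vehicle. The mucin gene MUC13 was 10.9-fold higher, GSG1 9.32-fold, EMP1 6.49-fold and SAT1 5.87-fold. The basal keratin gene KRT14 was at 0.04 FPKM with vehicle, 2.01 FPKM at 5 µM and 4.87 FPKM at 10 µM. SH3BGR was 7.31-fold higher, with 74.1% of its 50-base sequences found in another gene. The lowest genes were again histone genes (HIST1H2BK, HIST1H2AC, HIST1H2BD and HIST3H2A), with PPP1R10 at 0.23 times vehicle, the SUMO protease gene SENP3 at 186.12, 121.18 and 61.61 FPKM, the photoreceptor matrix gene IMPG2, and the multicopy or read-through genes GAGE12D and NME1-NME2. The near-identical histone genes HIST1H4J and HIST1H4K took opposite extremes at both doses: HIST1H4J was at 11.32 FPKM with vehicle and listed at 0 in both treated libraries, and HIST1H4K was listed at 0 with vehicle and at 8.31 and 4.23 FPKM with BAS. Their sum was 11.32, 8.31 and 4.23 FPKM. In all, 151 genes were at least 2-fold higher and 74 at least 2-fold lower, and at a 4-fold limit 18 and 4. With a pseudocount of 0.1 the counts were 273 and 145, and with trends in GC content and transcript length removed the split was 106 higher and 88 lower. Of the 221 called genes with a matched transcript, 19 (8.60%) share at least 50% of their 50-base sequences with another gene. Among all matched genes the share was 2.38%.

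**Figure D1:**
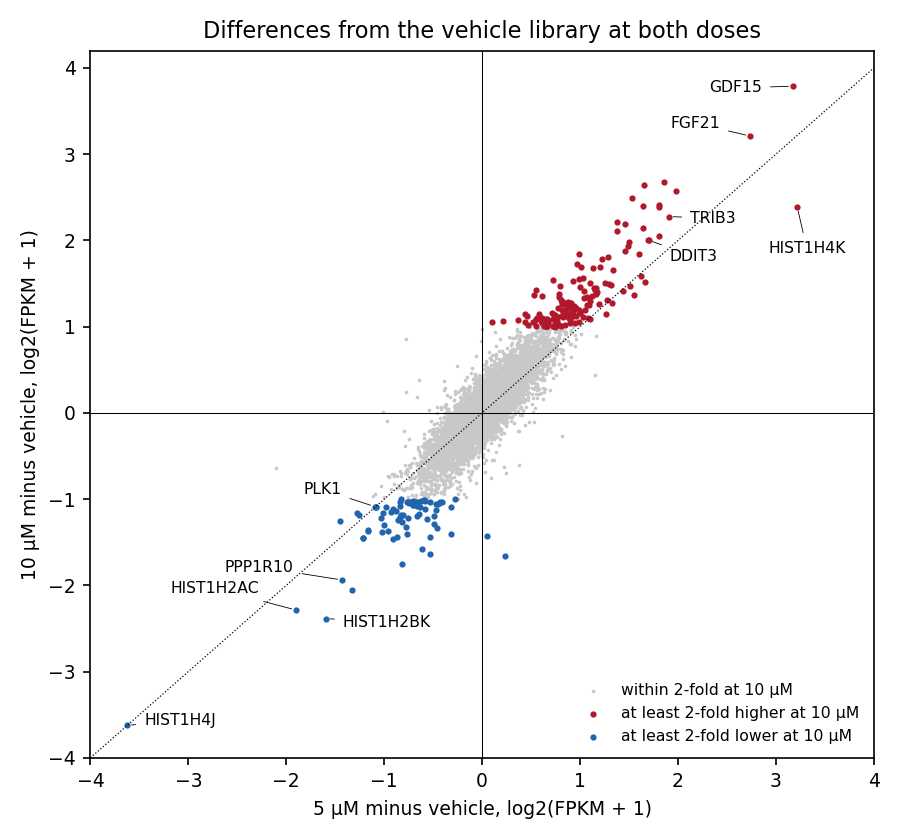
Differences from vehicle of log2(FPKM + 1) at 5 µM (horizontal axis) and 10 µM (vertical axis) for 11512 genes, 1 point per gene, with the dotted line marking equal differences. The 151 genes at least 2-fold higher at 10 µM are red and the 74 at least 2-fold lower are blue, and most of them lie on the same side of vehicle at 5 µM.

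Before the data were examined, 40 gene lists were fixed, of which 35 had at least 5 measured members. For each list, the median difference is given with its percentile among 10000 random lists of the same size and expression, and a list is said to stand apart where it lies outside the central 95% of these. At 5 µM 13 lists stood apart as higher and 7 as lower, and at 10 µM 12 as higher and 6 as lower, where 1.75 lists would by chance, though lists share members and genes are not independent.

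**Figure D2:**
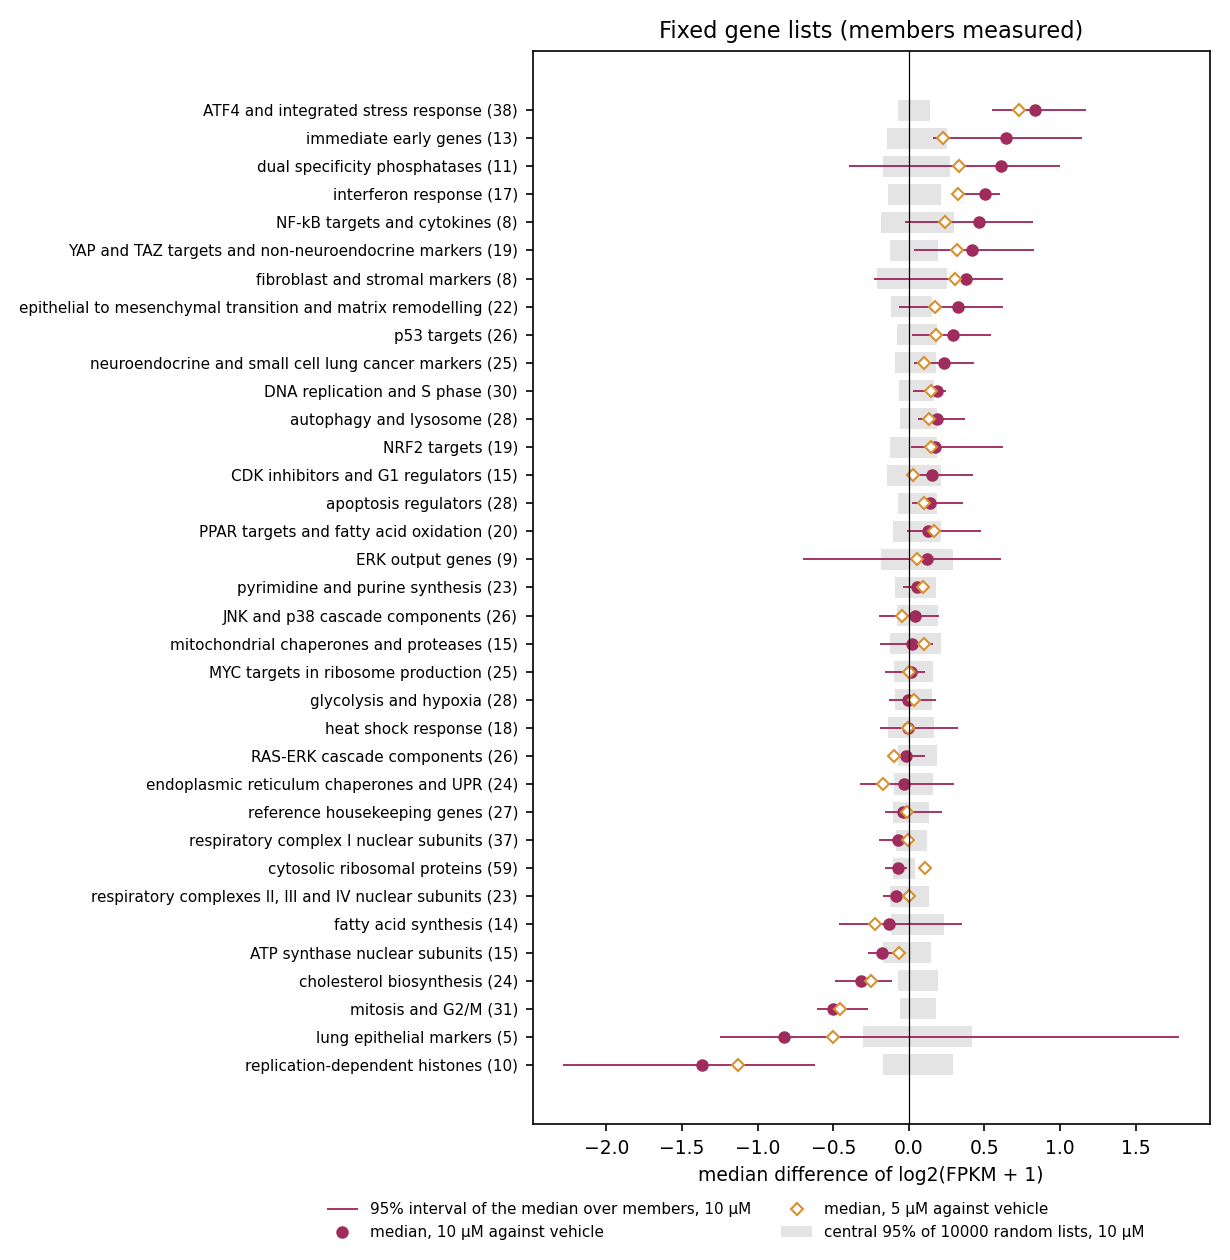
Median difference of log2(FPKM + 1) from vehicle over the measured members of each of the 35 lists, at 10 µM (filled circles, with the 95% interval of the median over members) and 5 µM (open diamonds). Grey bars hold the central 95% of 10000 random lists at 10 µM, and the ATF4 list lies highest at 0.83 and the histone list lowest at −1.37.

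Genes controlled by ATF4, the transcription factor of the integrated stress response to amino acid lack, heme lack, mitochondrial faults or misfolded protein, were higher as a group. Of the 38 members, 11 were at least 2-fold higher at 5 µM and 16 at 10 µM, with 0 at least 2-fold lower at either dose. The list median was 0.73 at 5 µM and 0.83 at 10 µM, above all 10000 random lists at both doses. Beside GDF15, FGF21 and TRIB3 (19.83, 77.31 and 99.98 FPKM), DDIT3 was at 11.99, 41.25 and 51.08 FPKM, and the asparagine synthetase gene ASNS at 75.40, 192.11 and 240.05 FPKM. CHAC1, which degrades glutathione, and DDIT4, an inhibitor of mTORC1, were 3.28-fold and 2.97-fold higher at 10 µM. The list of endoplasmic reticulum chaperones and unfolded protein response genes differed from it. Its median was −0.17 at 5 µM (percentile 0.03) and −0.03 at 10 µM (percentile 17.5). Within it, HERPUD1 and XBP1 were 1.74-fold and 1.58-fold higher at 10 µM, while HSP90B1, an abundant chaperone of this compartment, was at 168.89, 117.37 and 123.10 FPKM, and SDF2L1 at 18.10, 12.96 and 11.59 FPKM. Mitochondrial chaperones and proteases stayed within the random lists, with medians of 0.10 and 0.02, although the transcription factor gene ATF5 was 2.09-fold higher at 10 µM and the protease gene LONP1 1.35-fold. The heat shock list had a median of −0.01 at each dose, with CRYAB 1.73-fold higher at 10 µM, HSPA1B, which shares 71.4% of its 50-base sequences with another gene, 1.57-fold higher, and HSPA8 and HSP90AB1 at 0.61 and 0.64 times vehicle.

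**Figure D3:**
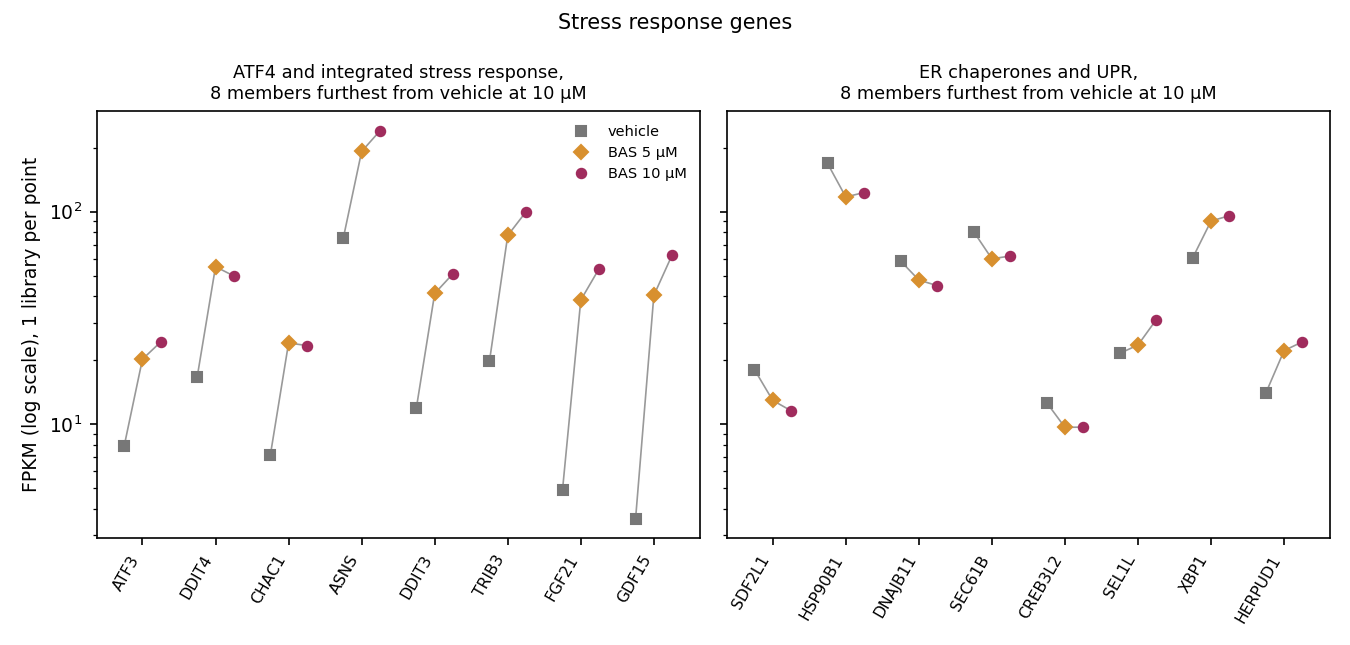
FPKM (log axis) in the vehicle, 5 µM and 10 µM libraries for the 8 ATF4 list members (left) and 8 chaperone and unfolded protein response members (right) with the furthest values from vehicle at 10 µM, 1 library per point. The 8 ATF4 list members lie above vehicle at both doses, GDF15 at 3.60, 40.43 and 62.59 FPKM, while HSP90B1, DNAJB11, SDF2L1, SEC61B and CREB3L2 lie below it.

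For the MAPK pathway, the readout genes of ERK, the kinase at the end of the RAS cascade, lay on both sides of vehicle. Of 9 measured ERK output genes, 5 were above vehicle and 4 below at 10 µM, and 0 differed 2-fold. DUSP4 (6.99, 4.96 and 3.67 FPKM), PHLDA1 (30.67, 20.71 and 18.51 FPKM) and SPRY2 (9.22, 8.51 and 6.76 FPKM) were lower, and ETV4 (8.90, 12.08 and 14.14 FPKM), ETV5 (18.35, 28.01 and 27.53 FPKM) and SPRY4 (2.81, 4.02 and 4.87 FPKM) were higher. DUSP6, a phosphatase gene induced by ERK, was at 41.64, 43.28 and 40.82 FPKM, CCND1 at 1.23, 1.21 and 1.42 FPKM and EPHA2 at 3.64, 5.43 and 4.15 FPKM. The list median was 0.05 at 5 µM and 0.12 at 10 µM (percentiles 66.1 and 70.3). With the filter raised to a mean of 5 FPKM it was −0.21 at 10 µM, at percentile 2.43. Immediate early genes, which growth factors and stress switch on within minutes to hours, were higher. Their median was 0.22 at 5 µM (percentile 99.2, and 93.1 with GC and length trends removed) and 0.64 at 10 µM (above all random lists), where each of the 13 measured members was above vehicle. ATF3 (7.92, 20.25 and 24.41 FPKM), FOS (0.33, 0.92 and 2.44 FPKM) and EGR1 (4.19, 6.02 and 10.49 FPKM) were at least 2-fold higher at 10 µM. ATF3 is also a member of the ATF4 list. Dual specificity phosphatases, which inactivate MAP kinases, had medians of 0.33 and 0.61 at 5 and 10 µM (percentiles 99.95 and 100), with DUSP2 2.37-fold, DUSP5 2.19-fold and DUSP1 1.89-fold higher at 10 µM and DUSP7 at 0.53 times vehicle.

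Of the ERK, MEK, JNK and p38 kinase genes, MAPK3 (ERK1) was at 29.40, 27.23 and 24.20 FPKM, MAP2K1 (MEK1) at 28.54, 33.36 and 37.31 FPKM and MAP2K2 (MEK2) at 89.23, 93.43 and 99.34 FPKM. MAPK8 (JNK1) was at 12.30, 10.44 and 10.98 FPKM and MAPK14 (p38α) at 19.20, 18.50 and 19.76 FPKM. Among the 26 RAS-ERK cascade components, 0 differed 2-fold at either dose. The list median was −0.10 at 5 µM (percentile 0.94, and 4.63 with GC and length trends removed) and −0.02 at 10 µM (percentile 14.9), with the receptor gene FGFR1 at 185.07, 133.92 and 107.65 FPKM and the RAS inhibitor gene NF1 at 0.65 times vehicle at 10 µM, and the receptor genes MET and FGFR4 each 1.47-fold higher. The JNK and p38 components had medians of −0.04 and 0.04 (percentiles 12.8 and 43.3), the latter −0.01 with median-ratio scaling. In that list GADD45A, a stress-induced activator of the upstream kinase MAP3K4, was at 34.29, 73.31 and 88.63 FPKM, and MAP2K6, a p38 kinase, at 7.45, 4.63 and 2.89 FPKM. RNA levels do not measure kinase activity.

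**Figure D4:**
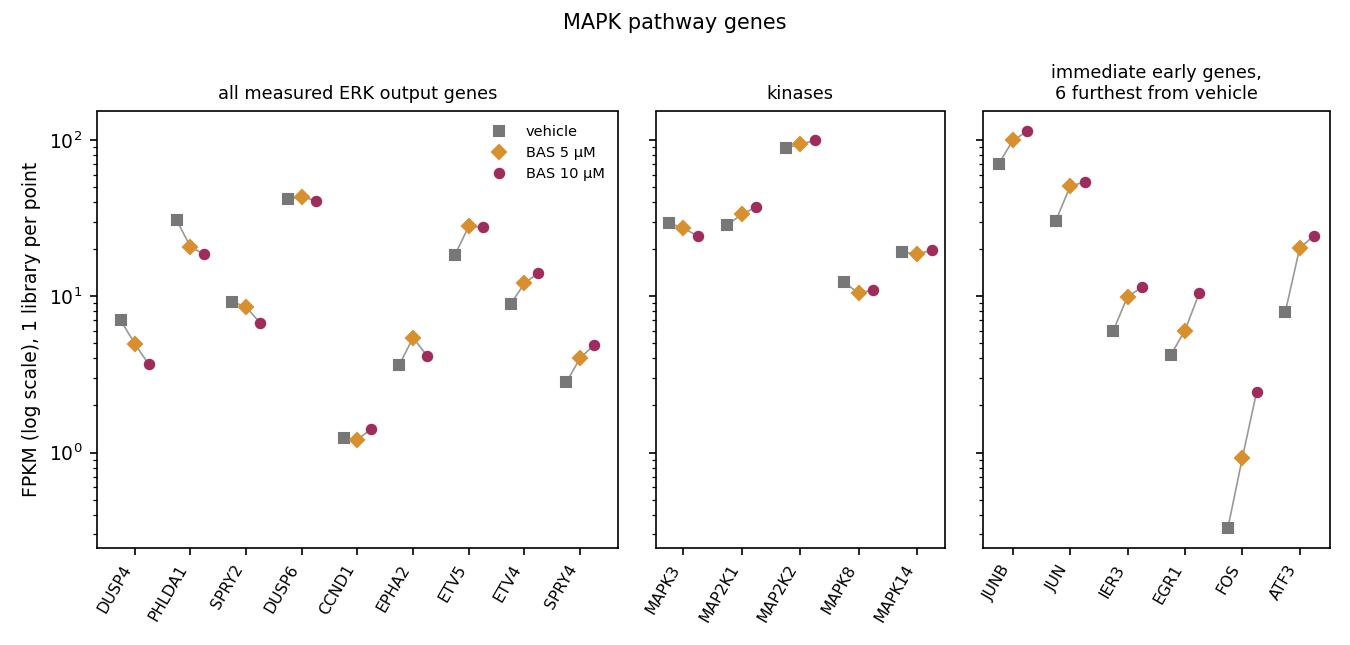
FPKM (log axis) in the vehicle, 5 µM and 10 µM libraries for the 9 measured ERK output genes (left), 5 kinase genes (middle) and the 6 immediate early genes furthest from vehicle at 10 µM (right), 1 library per point. ERK output genes lie on both sides of vehicle, DUSP4 at 6.99, 4.96 and 3.67 FPKM and SPRY4 at 2.81, 4.02 and 4.87 FPKM, while the 6 immediate early genes lie above it.

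Genes of cell division were lower, and those of DNA synthesis were slightly higher by their list median, with members on both sides of vehicle. Of 31 mitotic and G2/M genes, 30 were below vehicle at 5 µM and 29 at 10 µM, and the medians of −0.45 and −0.50 lay below all random lists. The spindle gene HMMR was at 17.06, 7.80 and 6.76 FPKM, the mitotic kinase gene PLK1 at 71.25, 32.74 and 33.04 FPKM, the kinesin gene KIF20A at 36.48, 16.27 and 18.22 FPKM, and CENPF at 23.25, 11.58 and 13.43 FPKM. The 30 genes of DNA replication and S phase had medians of 0.15 and 0.19 (percentiles 98.9 and 99.0), with 23 members above vehicle at each dose. With GC and length trends removed, the 10 µM median was 0.09. The thymidine kinase gene TK1 was at 63.86, 96.75 and 100.84 FPKM, and E2F1 and RRM2 were 1.47-fold and 1.39-fold higher at 10 µM. The 7 members below vehicle at each dose included MCM2 (101.78, 98.97 and 79.93 FPKM), PCNA (191.34, 176.1 and 166.37 FPKM) and POLA1 (14, 11.91 and 11.34 FPKM). By the mean, 0.15 at each dose, this list was within the random lists at both doses (percentiles 97.3 and 93.5). Histone genes of the replication-dependent clusters were far lower. Of 10 measured members, 8 were at least 2-fold lower at 5 µM and 7 at 10 µM, with medians of −1.13 and −1.37. HIST1H2BK was at 69.20, 22.26 and 12.44 FPKM, HIST1H2AC at 18.15, 4.12 and 2.93 FPKM, HIST1H2BD at 22.66, 8.44 and 4.72 FPKM and HIST1H1C at 67.94, 32.89 and 25.55 FPKM. HIST1H2BK, HIST2H4A and HIST2H2AA3 share at least 50% of their 50-base sequences with another gene and are uncertain for that reason. Cyclin-dependent kinase inhibitors and G1 regulators stayed within the random lists at both doses, with medians of 0.03 and 0.15, and at 10 µM lay outside them with quantile normalization (percentile 99.1). In that list CDKN2B (p15) was at 8.97, 14.70 and 19.04 FPKM and CDKN1A (p21) at 155.92, 158.99 and 202.17 FPKM.

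**Figure D5:**
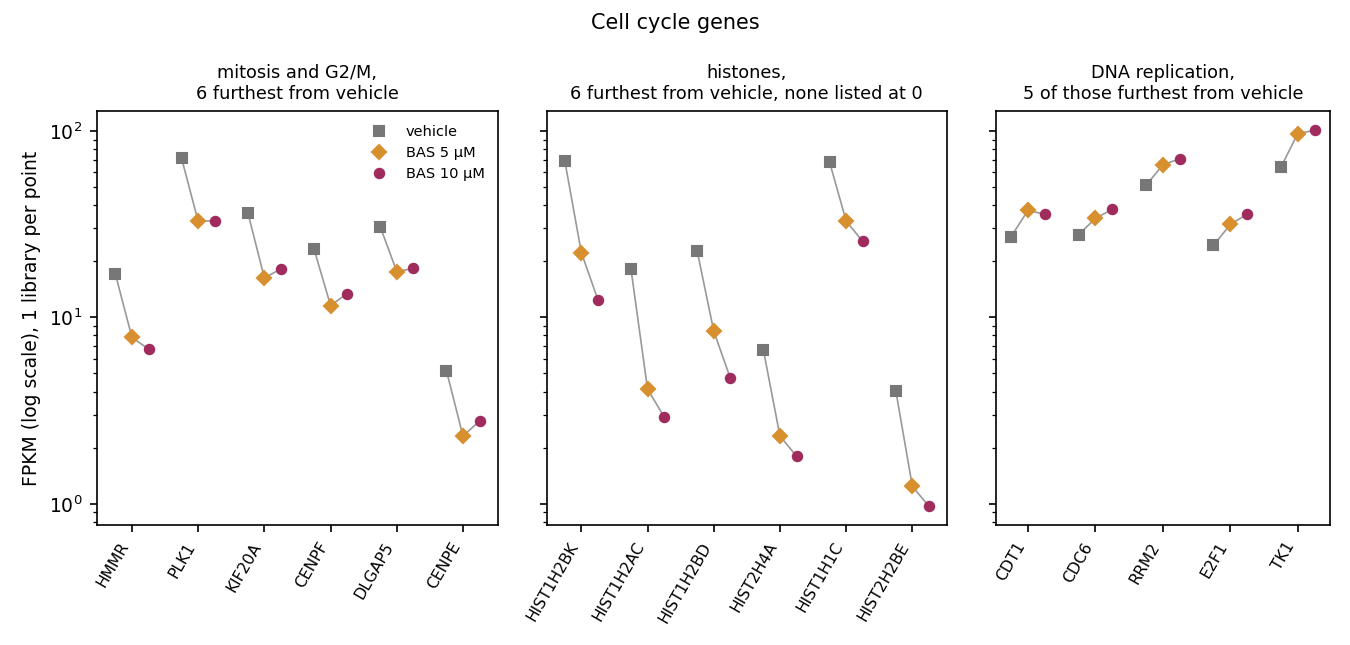
FPKM (log axis) in the vehicle, 5 µM and 10 µM libraries for 6 mitotic and G2/M genes, 6 histone genes and 5 DNA replication genes, among those of each list furthest from vehicle at 10 µM, 1 library per point. The 6 mitotic and 6 histone genes lie below vehicle at both doses, HIST1H2BK at 69.20, 22.26 and 12.44 FPKM, and the 5 DNA replication genes above it.

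The p53 target list, genes switched on by DNA damage and other stress, was higher, with medians of 0.18 and 0.29 (percentiles 99.7 and 99.9), but GDF15 and SESN2 (14.50, 30.23 and 28.12 FPKM) are shared with the ATF4 list, and with members of that list left out the 10 µM median was 0.18 at percentile 96.9. TP53I3 was 2.22-fold and PLK3 2.19-fold higher at 10 µM, and the DNA repair gene XPC was at 0.52 times vehicle. Of 28 apoptosis regulators, the pro-apoptotic BMF (4.63, 9.16 and 12.46 FPKM) was at least 2-fold higher at 10 µM, PMAIP1 (NOXA) was 1.64-fold and CASP8 1.56-fold higher, and the list medians of 0.10 and 0.14 stayed within the random lists. The means of the apoptosis list, 0.17 and 0.22, were outside them (percentiles 99.1 and 98.6). Autophagy and lysosome genes had medians of 0.13 and 0.18 (percentiles 97.6 and 97.6), led by the cargo receptor gene SQSTM1 (79.09, 138.64 and 174.24 FPKM) and MAP1LC3B (19.24, 29.78 and 39.08 FPKM), with GPNMB and NEU1 1.72-fold and 1.63-fold higher. The autophagy calls were lost in 7 alternatives at 5 µM and 3 at 10 µM, with the filter at 5 FPKM at percentiles 91.0 and 95.7. NRF2 targets, the antioxidant genes, were just inside the random lists, with medians of 0.14 and 0.17 (percentiles 96.9 and 96.5), and outside them with no filter (99.5 and 99.1). NQO1 was 2.21-fold higher at 10 µM and the ferritin genes FTL and FTH1 1.67-fold and 1.60-fold, while TXNRD1 was 1.61-fold higher. With 3 measured members, the metallothionein list had no median: MT2A was at 20.01, 35.38 and 57.26 FPKM, MT1X at 12.70, 26.37 and 29.82 FPKM and the zinc exporter gene SLC30A1 at 6.62, 7.67 and 12.76 FPKM.

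Among metabolic lists, cholesterol biosynthesis was lower at both doses, with medians of −0.25 and −0.31, below all random lists, and 22 of 24 members under vehicle at 10 µM. HMGCS1, which makes the substrate of HMG-CoA reductase, was at 45.42, 28.46 and 27.76 FPKM, INSIG1 at 25.93, 16.23 and 14.89 FPKM, HSD17B7 at 11.84, 7.69 and 5.54 FPKM and MVD at 11.79, 9.27 and 6.59 FPKM. Fatty acid synthesis genes had medians of −0.23 and −0.13 (percentiles 0.04 and 1.91), with SCD, ACACA and SREBF1 at 0.70, 0.68 and 0.71 times vehicle at 10 µM and FADS1 1.71-fold higher. With the mean in place of the median, that list was inside the random lists at both doses (percentiles 3.95 and 7.91). The PPAR target and fatty acid oxidation list stood apart at 5 µM (median 0.17, percentile 98.1, and 92.8 with no filter) and not at 10 µM (0.13, percentile 83.0, and 98.1 by the mean), with the fatty acid transporter gene CD36 at 0.78, 1.60 and 3.79 FPKM and UCP2 and FABP3 1.81-fold and 3.05-fold higher at 10 µM. Glycolysis and hypoxia genes had medians of 0.04 and −0.01, whose members split: VEGFA (6.45, 15.64 and 19.33 FPKM), ADM, HK1 and PDK1 were 3.00-fold, 2.17-fold, 1.80-fold and 1.84-fold higher at 10 µM and GAPDH was at 0.75 times vehicle. Nuclear genes of the respiratory chain were close to vehicle. Complex I had medians of −0.01 and −0.07 (percentiles 12.7 and 4.91, the latter 1.71 with unmatched random lists) and complexes II, III and IV of 0.00 and −0.09 (percentiles 24.8 and 7.77). The ATP synthase list had medians of −0.07 and −0.18 (percentiles 4.27 and 1.86, the latter 5.07 with GC and length trends removed), with ATP5MC3 at 60.70, 51.46 and 43.56 FPKM. UQCRFS1, the iron-sulfur subunit of complex III, was at 104.49, 94.99 and 86.02 FPKM, and DHODH, the mitochondrial enzyme of pyrimidine synthesis, at 6.19, 6.27 and 6.01 FPKM. Pyrimidine and purine synthesis genes had medians of 0.09 and 0.05, MYC targets in ribosome production of 0.00 and 0.02 and reference housekeeping genes of −0.01 and −0.04, each within the random lists. MYC itself was at 35.07, 33.17 and 38.82 FPKM.

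Neuroendocrine and small cell lung cancer markers were within the random lists at 5 µM (median 0.10, percentile 90.5) and apart at 10 µM (0.23, percentile 99.6), where 18 of 25 were above vehicle. The granule protein gene CHGA was at 1.91, 4 and 6.41 FPKM and UCHL1 at 82.21, 131.19 and 176.51 FPKM, while the transcription factor genes POU4F1 and NEUROD1 were at 101.29, 69.87 and 65.66 FPKM and at 104.96, 93.15 and 91.62 FPKM. At 10 µM the list was at percentile 96.6 with the filter at 5 FPKM and 94.9 with no filter. YAP and TAZ targets and non-neuroendocrine markers had medians of 0.32 and 0.42, above all random lists, with CYR61 at 66.56, 168.90 and 162.78 FPKM and CTGF at 0.94, 1.93 and 2.44 FPKM. Matrix remodelling and mesenchymal genes had medians of 0.17 and 0.33 (percentiles 99.6 and 99.99), with TNC at 2.85, 5.80 and 8.23 FPKM and MMP14 2.48-fold higher at 10 µM. The fibroblast and stromal marker list, with 8 measured members of which COL1A1 and COL3A1 are also in the matrix list, had medians of 0.31 and 0.38 (percentiles 99.7 and 99.7), with COL3A1 at 297.04, 433.94 and 453.79 FPKM. At 10 µM the fibroblast list was at percentile 94.0 with no filter and 96.0 by the mean. Interferon response genes had medians of 0.33 and 0.51, above all random lists, with ISG15 at 4.71, 10.31 and 10.82 FPKM and IFIT3 at 1.71, 2.72 and 3.91 FPKM, while OAS1 was at 926.48, 665.92 and 519.07 FPKM. NF-κB targets and cytokines had medians of 0.24 and 0.46 (percentiles 98.2 and 99.9) over 8 members, with LIF 2.09-fold and CSF1 1.81-fold higher at 10 µM. With the filter at 5 FPKM that list was inside the random lists at both doses. Of 5 lung epithelial markers, KRT8, KRT18 (2.83, 0.60 and 0.68 FPKM) and KRT19 were lower at both doses and KRT7 (5.74, 14.77 and 22.26 FPKM) higher, and the medians were −0.50 and −0.83. The mean of these markers at 10 µM, −0.25, was at percentile 3.89. Markers of blood and liver cells were near the floor: 2 of 18 immune markers passed the filter (CD68 at 2.85, 6.05 and 7.34 FPKM and PTPRC at 1.03, 0.92 and 1.09 FPKM), 0 of 12 erythroid and platelet markers and 1 of 15 hepatocyte markers (FGG at 4.27, 4.80 and 3.71 FPKM). None of the 13 mitochondrially encoded genes was among the symbols used.

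Between 10 µM and 5 µM, a comparison free of the vehicle library, the largest group difference among the lists was again in histone genes, with a median of −0.30, below all random lists. Immediate early genes were higher at the higher dose, with a median of 0.19 (percentile 99.9) and 13 of 13 members above their 5 µM value, as were the ATF4 list (0.11, above all random lists), YAP and TAZ targets (0.14, percentile 99.9), dual specificity phosphatases (0.17, percentile 99.0), RAS-ERK components (0.10, percentile 99.1), G1 regulators (0.12, percentile 98.6), NRF2 targets (0.09, percentile 97.9) and p53 targets (0.11, percentile 97.7). Among these, RAS-ERK components were at percentile 95.1 with GC and length trends removed, G1 regulators at 97.4 with no filter, NRF2 targets at 90.4 with quantile normalization, YAP and TAZ targets at 97.3 by the mean, and p53 targets at −0.0509 and percentile 2.34 with the filter at 5 FPKM, so these calls depend on the setting. ERK output genes (−0.08, percentile 2.40), cholesterol biosynthesis (−0.05, percentile 0.93), complex I (−0.10, percentile 0.08) and complexes II, III and IV (−0.11, percentile 1.03) were lower. The ERK output call was lost in 7 alternatives, at percentiles of 2.60 to 4.78, and those of cholesterol biosynthesis (percentile 3.13) and complex I (percentile 2.61) with GC and length trends removed. In the values as deposited, each of the 59 cytosolic ribosomal protein genes was lower at 10 µM than at 5 µM, with a median of −0.18. For example, RPL24 was at 1119.98, 981.69 and 750.07 FPKM and RPL7A at 2331.51, 2279.46 and 1692.03 FPKM. Against vehicle the median of that list was 0.11 at 5 µM (percentile 98.7) and −0.07 at 10 µM (percentile 13.9). With quantile normalization, the median was 0.01 at 5 µM (percentile 61.0) and the dose difference −0.03 (percentile 9.53), and by the mean the 10 µM value was −0.10 (percentile 0.89). The other lists were within the random lists in the main setting, and 6 of them lay outside in some alternatives. Neuroendocrine markers were higher with quantile normalization (percentile 99.3), by the mean (99.9), with GC and length trends removed (98.8) and among genes with under 50% shared sequence (99.4), matrix genes with quantile normalization (99.9) and by the mean (99.97), chaperones and unfolded protein response genes with quantile normalization (97.7) and with GC and length trends removed (98.2), interferon response genes with no filter (98.3) and autophagy genes by the mean (97.6). The ATP synthase list was lower with no filter (percentile 2.21), with unmatched random lists (0.16) and with GC and length trends removed (2.27). Of single genes, 5 were at least 2-fold higher at 10 µM than at 5 µM and 5 lower. BCL2L2-PABPN1, DHRS2, MAGEA2B, URGCP-MRPS24 and a symbol that is a number were higher, IMPG2, FAM72C, GAGE12D, KCNJ4 and MAGEA2 were lower, and 6 of the 9 with a matched transcript share at least 50% of their 50-base sequences with another gene. DHRS2, a short-chain dehydrogenase gene, was at 8.70, 5.20 and 11.66 FPKM and KCNJ4, a potassium channel gene, at 8.97, 6.99 and 2.77 FPKM. The split of 5 and 5 was 2 higher and 7 lower with median-ratio scaling, 2 and 6 with quantile normalization and 17 and 11 with each library rescaled to a common total.

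Genes 2-fold apart from vehicle at the lower dose were mostly so at the higher dose. Of the 62 genes at least 2-fold higher at 5 µM, 59 were so at 10 µM, which is 95.2%, and of the 24 lower, 18 were, which is 75%. Independent lists of these sizes would share 0.813 and 0.154 genes. Simulated unchanged libraries set against the same vehicle library shared 0 and 0, but none of their genes passed the 2-fold limit at either dose, so these counts give no support to the overlap. Across genes, which are not independent replicates, the differences at the doses had a correlation of 0.88 against 0.50 in the simulation, and a covariance of 0.0962 against 0.0111. Both comparisons use the 1 vehicle library, so part of the excess may come from that library. The 5 µM value lay between vehicle and 10 µM for 142 of the 151 higher genes (94.0%) and 67 of the 74 lower genes (90.5%). A simulation with the 5 µM library like vehicle or like 10 µM gave about 50%, a value fixed by its symmetric noise. It left out that these genes were chosen by their 10 µM difference, which by itself raises the share. The 50% is therefore not a chance level for 94.0% and 90.5%. Among the genes with 5 µM in between, GDF15, FGF21, MUC13 and GSG1 were among the highest and HIST1H2BK, HIST1H2AC, HIST1H2BD, PPP1R10 and NME1-NME2 were the lowest. At 5 µM the higher genes had reached a median of 71.8% of their 10 µM difference and the lower genes 65.5%, values that the choice of genes at 10 µM also affects.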

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

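All the tests of explanations in this part were chosen after the results were seen. Each result here lay on opposite sides of vehicle at the doses. With 1 library per group, none of these differences between doses was tested. The cytosolic ribosomal protein list had a median of 0.11 at 5 µM and −0.07 at 10 µM against vehicle, a difference between doses of −0.18. With quantile normalization its 5 µM median was 0.01, at percentile 61.0, and the difference between doses −0.03, at percentile 9.53. With that scaling the 5 µM median was still above 0, but neither value stood apart from random lists. Nuclear subunits of respiratory complexes II, III and IV had medians of 0.00 and −0.09 and a difference between doses of −0.11. With median-ratio scaling, the 5 µM median of that list was −0.02, on the same side of vehicle as at 10 µM.

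Of single genes, BCL2L2-PABPN1 was −0.77 on the log2 scale at 5 µM and 0.85 at 10 µM, and 1.63 between doses. DHRS2 was −0.65 and 0.38, and 1.03 between doses. MAGEA2B was −1.02 and 0.01, and 1.03 between doses. URGCP-MRPS24 was −0.78 and 0.25, and 1.02 between doses. FAM72C was 0.05 and −1.43, and −1.48 between doses. IMPG2 was 0.23 and −1.65, and −1.88 between doses. MAGEA2 was 0.82 and −0.26, and −1.08 between doses.

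For the 10 genes 2-fold apart between 10 µM and 5 µM, reads divided differently between near-identical copies or read-through transcripts are a candidate explanation that stays open. Of the 9 genes with a matched transcript, 6 share at least 50% of their 50-base sequences with another gene, which is 66.7% against 2.38% of all matched genes. Whether the sum with the partner genes held between doses does not decide it, because for 0 of these 6 would that sum have differed 2-fold with the partners kept at their 5 µM values. MAGEA2 and MAGEA2B moved in opposite directions and summed to 40.17, 39.64 and 37.63 FPKM in the vehicle, 5 µM and 10 µM libraries, while the partners of FAM72C were lower at 10 µM as it was, at 15.24 and 12.94 FPKM. A mean under 5 FPKM is argued against as the whole cause, since 4 of the 10 genes had a mean of at least 5 FPKM. Of these, MAGEA2 and MAGEA2B are the near-identical pair above, which leaves DHRS2 (8.52 FPKM) and KCNJ4 (6.24 FPKM). With the depth unknown, noise from few reads stays open for these as well. DHRS2, IMPG2 and KCNJ4 share under 50% of their sequence, and for these dose itself stays open, as untested.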

How the results depend on the processing

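The removal of GC and length trends, the limit to genes with under 50% shared 50-base sequences and the lists without ATF4 list members were chosen after the results were seen. For the 10 counts of genes, 70 of 120 alternative values were within 1.5 times the reported count and 50 were not, and the numbers of lists standing apart were within that range in 78 of 78. For the list medians, 1251 of 1362 alternatives gave a value near the reported one, 110 moved and 1 reversed. For the differences of named genes, 2688 of 2730 stayed near and 42 moved. At 10 µM over 13 settings, the ATF4 list median ranged from 0.74 to 0.99, mitosis and G2/M from −0.56 to −0.46, replication-dependent histones from −1.74 to −1.09, cholesterol biosynthesis from −0.38 to −0.31, immediate early genes from 0.39 to 0.70 and dual specificity phosphatases from 0.41 to 0.63, each outside the random lists in all 13. ERK output genes ranged from −0.21 to 0.18, RAS-ERK cascade components from −0.08 to 0.01, p53 targets from 0.18 to 0.39 and DNA replication and S phase from 0.09, with GC and length trends removed, to 0.20. With the 3 scalings, the median difference of all genes lay between −0.03 and 0.08 over the comparisons. The read depth is unknown, so what depth limits cannot be given, and no paired analysis was possible because there was 1 library per group.

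Counts are given as higher and lower. With a pseudocount of 0.1, they were 143 and 53 at 5 µM against vehicle, 273 and 145 at 10 µM against vehicle, 23 and 18 between doses, 129 and 35 at both doses, and 253 and 127 ordered by dose. With a pseudocount of 0.5, they were 16 and 11 between doses, and 28 genes were lower at both doses. A smaller pseudocount shrinks the differences of low genes less. With no filter, 8 genes were higher between doses. With a filter at 5 FPKM, which leaves fewer genes, 13 were lower at 5 µM, 95 higher and 42 lower at 10 µM, 2 and 2 apart between doses, 11 lower at both doses, and 90 and 40 ordered by dose. The 1.5-fold limit gave 346 and 184 at 5 µM, 695 and 396 at 10 µM, 50 and 47 between doses, 296 and 151 at both doses, and 651 and 346 ordered by dose. The 4-fold limit gave 3 and 2, 18 and 4, 0 and 0, 3 and 1, and 17 and 3 in the same order.

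With median-ratio scaling 2 genes were higher between doses, and with quantile normalization 2. Rescaling to a common total gave 41 lower at 5 µM, 17 and 11 between doses, and 31 lower at both doses. With under 50% shared 50-base sequences, 1 and 2 were apart between doses. The ERK output list median at 10 µM was −0.21 with the filter at 5 FPKM, at percentile 2.43, and the p53 list median between doses was −0.0509 in place of 0.11. The mean of the DNA replication list was 0.15 at each dose, at percentiles 97.3 and 93.5. Without ATF4 list members, the p53 list median at 10 µM was 0.18, at percentile 96.9. Apart from settings with fewer genes or another limit, the cause was not tested.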

Other observations

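The genes of the first paragraph and all the tests of explanations in this part were chosen after the values were seen. Keratin genes divided: of 12 measured, 4 were at least 2-fold higher than vehicle at both doses and 2 lower. KRT80 was at 39.17, 112.28 and 157.53 FPKM in the vehicle, 5 µM and 10 µM libraries and KRT16 at 0.23, 2.20 and 4.71 FPKM, beside KRT7 and KRT14, while KRT8 and KRT18 were the lower pair. TXNIP, an inhibitor of thioredoxin, was at 14.90, 42.73 and 71.85 FPKM, the transcription factor gene KLF2 at 10.35, 33.36 and 39.82 FPKM, and TSC22D3 (GILZ), a glucocorticoid-induced gene, at 14.04, 41.95 and 40.66 FPKM. The protease inhibitor gene CSTA was at 10.08, 33.72 and 47.80 FPKM, the apolipoprotein gene APOC1 at 6.31, 22.70 and 28.40 FPKM and the inhibin subunit gene INHBE at 29.64, 82.16 and 80.50 FPKM. PTPRZ1, a receptor phosphatase gene, was lower, at 17.30, 7.17 and 6.11 FPKM. The 8 measured nuclear genes that resemble the mitochondrial humanin sequence were above vehicle at both doses in the values as deposited, MTRNR2L4 by 0.01 at 10 µM, with medians of 0.46 and 0.59, and MTRNR2L2, the most abundant gene at both doses, was at 5488.94, 7725.21 and 8512.11 FPKM. With no mitochondrially encoded genes among the symbols used, mitochondrial RNA read as these genes could not be told from their own RNA.

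A higher ATF4 list at both doses was not removed by correction for GC content and transcript length, after which the median at 10 µM was 0.74, above all random lists. A vehicle library apart from the treated ones for another reason cannot be told apart from the treatment, because there was 1 vehicle library. Between doses, without that library, the median was 0.11 with an interval of 0.04 to 0.21, above 0 but far under the difference from vehicle. Endoplasmic reticulum stress with chaperones still raised as a group at 48 h is argued against at 5 µM. There the chaperone and unfolded protein response list had a median of −0.168 with an interval of −0.21 to 0.12, all under a 1.2-fold rise. It stood below the random lists (percentile 0.03) while the ATF4 list was at 0.73. Of the 24 chaperone and unfolded protein response members, 16 were below vehicle at 5 µM and 8 above. HERPUD1 and XBP1 were 1.58-fold and 1.49-fold higher. This verdict covers the level of that list alone, and the interval over members carries no error between libraries. At 10 µM a raised chaperone list stays open, since the median was −0.0306 with an interval of −0.32 to 0.30. Stress of this compartment without raised chaperones was not tested.

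Lower mitotic genes at 10 µM were likewise not removed by correction for GC content and transcript length, with a median of −0.46, below all random lists. Fewer cycling cells stay open, because the DNA replication list and the replication-dependent histone list went apart. Whether the histone values follow the number of cells in S phase in these libraries was not tested. The DNA replication list had a median of 0.19 with an interval of 0.03 to 0.25, and 0.09 with GC and length trends removed, while the replication-dependent histone list had a median of −1.37, below all random lists. Cell cycle phases were not analysed here.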
